A study of Mus musculus with 3 samples.

How the data were processed

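Total RNA of 3 mouse cell samples was labelled with Cy3 and hybridised to 1-colour Agilent whole mouse genome arrays of 1 probe design, with 1 array per group. The groups were mouse embryonic fibroblasts (MEF) that the labels call p53-null, embryonic stem (ES) cells, and MEF that the series design calls wild type for p53. All carried a Nanog-GFP reporter, per the labels.

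The deposited scanner files hold spot intensities on a linear scale, which the authors obtained with Agilent Feature Extraction 9.5.3.1, per the file headers. The processed signal in them is the Cy3 intensity after subtraction of the background and correction for spatial and multiplicative trends across the array, per the file headers. Nothing in it makes arrays comparable with each other. The authors' value table of the whole series held the same intensities for 45018 features, with ratios to the processed signal between 0.995 and 1.005 on each array, so it carried neither a log scale nor a centring. Its columns had medians of 51.8 for the p53-null MEF, 50.0 for the ES cells and 43.2 for the MEF. It has no direction, being 1 signal per array.

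For each array, log2 of the processed signal was taken and the 75th percentile over 43379 non-control spots was subtracted. The 1639 control spots were left out, as were 62 spots of the p53-null MEF array, 176 of the ES cell array and 192 of the MEF array that the scanner software marked as uneven or as outliers. Spots of 1 probe were averaged. Of 41174 probes, 41050 had a value on all 3 arrays. A probe counted as well above background where at least 50% of its kept spots carried that mark in the file. Where a gene had several probes, the probe with the highest mean log2 signal over the 3 arrays stood for it. The difference of 2 arrays was taken as measured where both were well above background. Where 1 of them was not, the bright signal was set against the higher of the dim probe's own signal and the lowest signal among probes well above background on the dim array, which gives a bound written as "at least". Where the dim probe's own signal was the higher, as for Sox10 and Igfbp5 below, the value equals the measured difference and is not a strict minimum. No fold was given where neither array was well above background.

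Probes were named with the RefSeq gene table of assembly GRCm38.p6, used for names alone. Of all probes, 24375 were matched through their accession, 6301 through a symbol and 2426 through a unique synonym, and 8072 kept the name in the array's design file. This gave 27537 gene labels, 19724 of them matched to RefSeq. Positions are those of the newer design file, on mouse build mm8. The files of the ES cell and MEF arrays cite build mm7, and no position was taken from them. Whether a probe lies in an exon or an untranslated region was not determined, because no genome of that build was used here.

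With 1 array per group there were no replicates, so no test, p-value or standard error between samples could be given, and each difference describes these arrays. The number of arrays limits the precision. Technical error came from 2 sources. The scanner software's error model sets 10% per bright signal. Among the 245 probes printed at 10 spots, those well above background in every spot had a standard deviation between spots of 5.09% on the p53-null MEF array, 5.29% on the ES cell array and 5.82% on the MEF array. Genes at least 5-fold different were counted in each direction. Gene lists were described by the median log2 difference of the members well above background on at least 1 array of the comparison, with bounds at their value. This median was placed among the medians of 10000 random lists of the same size, drawn with replacement from genes in the same 20 classes of mean signal. A list was said to stand apart below percentile 2.5 or above percentile 97.5.

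The 29 lists and the rule for named genes were fixed before the data were examined. The lists were genes that p53 is known to activate, genes followed up by the study as far as remembered, CDK inhibitors with Rb family genes, G2 and mitosis genes, replication genes, pluripotency genes, factors used to make induced pluripotent stem (iPS) cells, extracellular matrix and fibroblast genes, mesenchymal transcription factors, epithelial genes, Hox genes, imprinted genes and chromatin genes. The others were interferon-stimulated genes, secreted inflammatory genes, TGF-beta and BMP genes, and genes of smooth muscle, skeletal muscle, bone and cartilage, adipocytes, macrophages, endothelium, the nervous system, early lineages and the germ line, with glycolysis and hypoxia genes, expression references, Xist with Y chromosome genes, and p53 with its relatives and regulators. The list of CDK inhibitors and Rb family genes also holds E2f, D-type cyclin and Cdk genes, so its median does not describe inhibitors alone. Of their 815 entries, 802 were on the array. Of the 52 p53-activated genes on the array, 3 are also among the genes remembered as followed up by the study, and 8 of the 13 iPS factors are also pluripotency genes. The named genes were Trp53, the followed-up genes and the iPS factors, the 8 largest and the 8 smallest differences measured on both arrays, the 4 largest bounds in each direction, and up to 4 members of each list with the largest difference. Genes with 2 probes at least 2-fold different in opposite directions were left out of the largest differences. Not every gene chosen by this rule is named in the text.

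Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the alternative normalizations with R 4.3.3 and limma 3.58.1. Figures were drawn with matplotlib 3.10.9. The steps were tested on simulated arrays made from the MEF array with the noise of its repeated spots. For p53-null MEF against MEF, over 27626 labels, 67 of 67 genes changed 8-fold and 66 of 66 changed 20-fold were counted in the right direction, as were 0 of 67 changed 3-fold and 0 unchanged genes. The changed genes were drawn from bright probes alone, and differences between slides, cultures and probes were left out. The simulation thus checks the steps and not the error of real calls. A list of 30 raised genes came to percentile 100 and one of 30 unchanged genes to percentile 37.9.

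Alternatives fixed beforehand were scaling by the median, by the 75th percentile of probes well above background on all arrays, by quantile normalization and by cyclic loess, normexp background correction of the mean spot signal with an offset of 50, the authors' value table, measured differences alone, no filter on dim probes, the mean of a gene's probes or the probe with the median difference, marked spots kept, thresholds of 2-fold and 10-fold, and random lists without matching. Alternatives chosen after seeing the data were no scaling between arrays, scaling on 235 spike-in spots, a correction for the GC content of the probes, genes matched to RefSeq alone, and the p53-null MEF array in place of the MEF array for the ES cells.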

Results

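Gene expression was measured on 3 arrays, 1 each for p53-null MEF, ES cells and MEF. MEF are primary fibroblasts from mouse embryos, and ES cells are pluripotent cells from the early embryo. The series asks what part p53 plays when fibroblasts are made into iPS cells, and its design pairs p53-null MEF with MEF and ES cells with MEF. The 75th percentile of the spot signal was 1040 units on the p53-null MEF array, 834 on the ES cell array and 829 on the MEF array. Spots well above background numbered 26198, 27954 and 26462 of 43379 in the same order, and no spot was saturated. The ES cell and MEF arrays lay on 1 slide and were scanned together. The p53-null MEF array lay on another slide, scanned separately, where the median local background was 44 units against 27 on each of the other arrays.

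Trp53, the gene for p53, was 29.1-fold lower in p53-null MEF than in MEF at its brighter probe, a difference of -4.87 ± 0.22 on the log2 scale (error model). With normexp correction this probe differed by -3.81 under 75th percentile scaling and -3.70 under quantile normalization. This probe, designed on transcript NM_011640 and placed at chromosome 11, 69405827 to 69405886 of mm8, was printed at 10 spots and gave 56.3 units in p53-null MEF, 1304 in MEF and 4902 in ES cells. The standard deviation over those spots was 3.85, 29.8 and 143 units in the same order. A second Trp53 probe, at 69396652 to 69396710 on the same chromosome, gave 260 units in p53-null MEF, 572 in MEF and 304 in ES cells, which is 2.76-fold lower in p53-null MEF. Both signals in p53-null MEF were well above background. The labels do not say which part of the gene was removed, so neither probe is known to lie inside it.

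**Figure D1:**
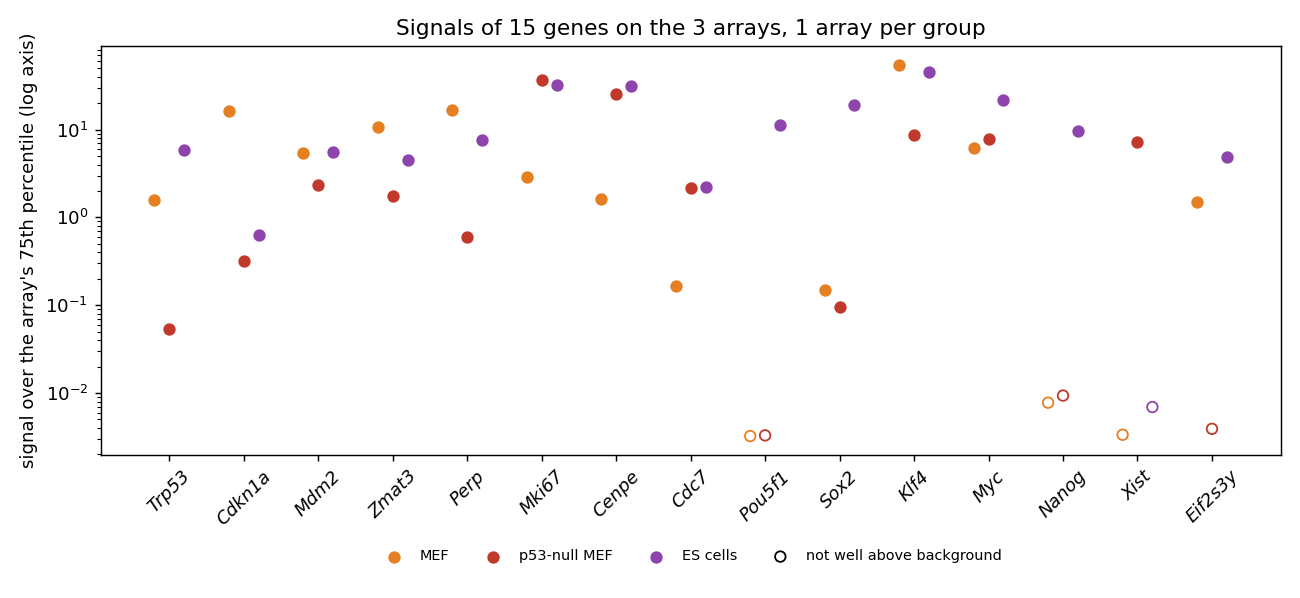
Signals of 15 genes on the 3 arrays, each as the processed signal divided by the 75th percentile of its array on a log axis, with 1 point per array, open where the probe was not well above background. Trp53 and Cdkn1a were lowest in p53-null MEF, Mki67, Cenpe and Cdc7 were lowest in MEF, and Pou5f1 and Nanog were well above background in ES cells alone.

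The comparison of p53-null MEF with MEF asks which genes differ with the loss of p53 in the fibroblasts from which iPS cells are made. Genes that p53 is known to activate were mostly lower in p53-null MEF. Cdkn1a, which encodes the CDK inhibitor p21, was 50.5-fold lower, with 335 units against 13478. The receptor gene Eda2r was at least 65.2-fold lower, the epoxide hydrolase gene Ephx1 32.0-fold lower and Perp, an effector of p53-dependent apoptosis, 28.1-fold lower. Genes of mitosis and DNA replication were higher in p53-null MEF, led by the kinesin gene Cenpe at 15.7-fold, the S phase kinase gene Cdc7 at 13.2-fold (2.63 on the log2 scale at another probe) and the proliferation marker Mki67 at 12.8-fold. Differences between bright signals carried an error of about 0.20 on the log2 scale from the error model, shown here by Cdkn1a at -5.66 ± 0.20.

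Of 51 measured genes activated by p53, 32 were at least 2-fold lower, 3 at least 2-fold higher and 16 neither. Their median log2 difference was -1.46, at percentile 0 of the random lists. Scaling on spike-ins moved the median of all genes to 2.02 and that of this list to 0.38. Its percentile stayed 0, nearly by construction, since the random lists shift with it. Of 5 genes that the study itself is remembered to have followed up, Zmat3, which encodes an RNA-binding zinc finger protein, was 6.10-fold lower and Mdm2, the ubiquitin ligase of p53, 2.33-fold lower, with another Mdm2 probe 10.8-fold lower. Arhgap18 was 2.06-fold higher, and Inmt was not well above background on either array. This list, with a median of -1.91 at percentile 0.0400, is not independent evidence, because it is remembered as chosen from these arrays. That recall was not checked against the study. Its median was 0.06 with scaling on spike-ins, and its percentile stayed the same nearly by construction.

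All 38 G2 and mitosis genes were at least 2-fold higher in p53-null MEF, with a median log2 difference of 2.28 at percentile 100. The spindle checkpoint kinase gene Ttk was higher by 3.58 on the log2 scale and the kinetochore gene Cenpf was 10.6-fold higher. Of 36 replication and G1/S genes, 32 were at least 2-fold higher and none at least 2-fold lower, with a median of 2.02 at percentile 100. Among them the DNA polymerase gene Pola1 was 11.1-fold higher, the primase gene Prim1 7.78-fold and the cyclin gene Ccne2 7.92-fold. Chromatin genes had a median of 0.81 at percentile 99.99 (97.3 with the mean of all probes, which ends the call), with 13 of 30 at least 2-fold higher, among them Hells, a remodelling factor used in DNA methylation, at 13.4-fold and Uhrf1, which recruits Dnmt1, at 4.08-fold. Among p53 and its relatives and regulators, with a median of 0.32, the checkpoint kinase gene Chek1 was 13.9-fold higher. The list of CDK inhibitors and Rb family genes, which also holds E2f, D-type cyclin and Cdk genes, had a median of 0.29. Its members went both ways, with Cdkn3 5.69-fold and Cdkn1b 4.82-fold higher and the cyclin gene Ccnd1 4.16-fold lower. A second Cdkn1b probe differed by 0.14 on the log2 scale.

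Extracellular matrix and fibroblast genes were lower in p53-null MEF, with a median log2 difference of -1.03 at percentile 0, and 20 of 38 were at least 2-fold lower and 0 higher. The collagen gene Col6a1 was 5.96-fold lower, the gelatinase gene Mmp2 5.80-fold and the proteoglycan gene Dcn 5.76-fold, while probes of Fn1, the fibronectin gene, differed from -2.74 to 1.41. Secreted inflammatory genes had a median of -0.62 at percentile 0.620, with the protease inhibitor gene Serpine2 57.9-fold, the chemokine gene Ccl8 38.9-fold, Igfbp3 14.4-fold and the collagenase gene Mmp13 13.7-fold lower, and another Igfbp3 probe at -1.42 on the log2 scale. Ccl8 had 18.8 units in p53-null MEF, near the lowest signal well above background on that array, 16.0 units. TGF-beta and BMP genes had a median of -0.52 at percentile 0.630, with Ltbp2, of the latent TGF-beta binding protein family, 13.8-fold lower. The glycolysis and hypoxia list, at -0.37 and percentile 0.3, had 21 of 29 genes within 2-fold. With scaling on spike-ins, which shifts all genes, the medians of these 4 lists were 0.94, 1.35, 1.40 and 1.61. Their percentiles of 0, 0.720, 0.310 and 0.3 could hardly move, since the random lists shift too. TGF-beta and BMP genes lost their call with the GC correction (percentile 4.89) and the glycolysis list with random lists not matched on signal (7.68).

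Factors used to make iPS cells had a median log2 difference of -0.92 at percentile 0.530 among 9 measured. Scaling on spike-ins, which moved the median of all genes to 2.02, gave 1.05 at the same percentile, since the random lists shift too. The list no longer stood apart without a filter on dim probes (percentile 3.34), with the mean of all probes (3.605) or with the median probe (2.64). Klf4 was 6.27-fold lower in p53-null MEF, Klf2 3.65-fold, Klf5 2.65-fold, Glis1 2.36-fold and Mycn 1.90-fold, and a second Klf2 probe differed by -0.07 on the log2 scale. Mycl was 2.62-fold higher. Values of Sox2, Sall4 and Myc were -0.63, -0.70 and 0.36. Pou5f1, Nanog, Esrrb and Lin28a were not well above background on either fibroblast array. The pluripotency list, at -0.51 and percentile 7.20, did not stand apart, although the cell cycle factor gene Mybl2 in it was 7.75-fold higher.

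Of the lists of markers of other cell types, those of bone and cartilage and of skeletal muscle stood apart between the fibroblast arrays. Bone and cartilage genes had a median of -1.14 at percentile 0.3, and with scaling on spike-ins they were at 0.83 and percentile 3.97 and no longer stood apart. Among them the cartilage matrix gene Comp was 18.0-fold, Col10a1 13.1-fold and the osteocalcin gene Bglap 9.18-fold lower in p53-null MEF. Skeletal muscle genes were at 0.60 and percentile 99.7, with 8 of 23 at least 2-fold higher, 3 lower and 12 neither. The troponin gene Tnni1 was 4.35-fold and the muscle regulator Myog 3.74-fold higher, and the calcium channel gene Ryr1 4.14-fold lower, with another Ryr1 probe at 0.23 on the log2 scale. Lists of macrophage, neural, adipocyte, endothelial and smooth muscle genes did not stand apart, although single members differed. Macrophage genes were at -0.75 and percentile 14.0, with 8 of 18 at least 2-fold lower and 2 higher. However, 12 of them entered as bounds, which never exceed the difference of the probes' own signals, and the median of the probes' own signals was -1.89. Among them the lysozyme gene Lyz2 was 19.7-fold lower and the myeloid receptor gene Trem2 at least 5.88-fold lower. Neural genes were at 0.14 and percentile 81.7, with the glial genes Sox10 13.9-fold and S100b 8.35-fold lower. The Sox10 fold rests on a signal not well above background in p53-null MEF. Adipocyte genes were at -0.30 and percentile 23.7, with the lipoprotein lipase gene Lpl 9.88-fold lower, endothelial genes at -0.61 and percentile 16.0, with Mmrn2 10.7-fold lower, and smooth muscle genes at -0.17 and percentile 17.2, with Myocd, the smooth muscle coactivator, 14.5-fold higher and Myh11 5.61-fold lower.

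The remaining lists did not stand apart between the fibroblast arrays either. Hox genes had a median of -0.75 at percentile 4.04, with Hoxc8 at least 12.8-fold lower and Hoxb13 4.75-fold higher. Hoxb13 had 14.5 units in MEF, near the lowest signal well above background on that array, 12.4 units. Interferon-stimulated genes were at -0.63 and percentile 3.34, with 12 of 37 at least 2-fold lower and 6 higher. They held the chemokine gene Cxcl10 at 15.5-fold and Oasl1 at 7.99-fold higher, and the immunoproteasome gene Psmb9 6.92-fold lower. Both of these lists stood apart in some alternatives, as with the mean of all probes (percentile 0.08 for Hox and 0.51 for interferon-stimulated genes). Imprinted genes were at -0.16, with Slc22a18 25.0-fold lower, by -1.93 on the log2 scale at another probe, and Phlda2 3.17 higher on that scale, or 1.92 at another probe. Medians were -0.26 for mesenchymal transcription factors, 0.07 for epithelial genes, 0.24 for early lineage genes, 0.06 for germ line genes and -0.05 for expression references. Among the last, Ywhaz was 6.80-fold higher at its brighter probe and differed by 0.24 on the log2 scale at another.

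Xist, the RNA that silences an X chromosome in female cells, was at least 479-fold higher in p53-null MEF, at 7437 units, and was not well above background in MEF. The Y chromosome genes Eif2s3y, Ddx3y and Kdm5d were at least 96.9-fold, 41.2-fold and 19.2-fold lower in p53-null MEF. The list of Xist and Y chromosome genes, whose members go both ways, had a median of -0.72. By these signals the fibroblast cultures seem to differ in embryo sex, which cannot be told apart from the p53 genotype here.

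Among single genes, the joint lubricant gene Prg4 was 434-fold lower in p53-null MEF and the proteoglycan gene Prelp 257-fold lower. Dglucy was 88.2-fold, the neurotrophin receptor gene Ngfr 61.7-fold and the Wnt antagonist gene Sfrp4 39.0-fold lower, with another Ngfr probe at -0.42 on the log2 scale. Ngfr had 19.8 units in p53-null MEF, near the lowest signal well above background on that array, 16.0 units. The synuclein gene Sncg and the receptor phosphatase gene Ptprv were at least 271-fold and 257-fold lower. Large measured increases belonged to the bicarbonate transporter gene Slc4a7 at 55.3-fold, the histone gene H2bu2 at 51.0-fold, the stathmin gene Stmn4 at 45.3-fold, the kinesin gene Kif20b at 28.2-fold, the importin gene Ipo7 at 26.7-fold, the kinesin gene Kifc5b at 25.7-fold and the retinoic acid receptor gene Rarb at 21.9-fold. Other probes of Slc4a7, Kif20b and Ipo7 differed by 0.86, 2.79 and 2.335 on the log2 scale. Dscam, Rims2 and Zfp874a were at least 25.3-fold, 16.9-fold and 15.3-fold higher.

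In all, 583 gene labels were at least 5-fold higher and 530 at least 5-fold lower in p53-null MEF, out of 17398 well above background on at least 1 array. Of these, 145 and 134 were counted by a bound. Among genes matched to RefSeq, 323 were higher and 495 lower. Differences of genes with several probes had a median standard deviation between probes of 0.40 on the log2 scale, and 81 matched genes had probes at least 2-fold apart in opposite directions. Slide, scan, group and the embryo sex read from Xist and Y chromosome genes cannot be told apart for p53-null MEF against MEF. The counts were 199 and 244 with normexp correction and 75th percentile scaling, 961 and 374 without scaling and 6554 and 60 with scaling on spike-ins. The share of higher labels was 52.4% in the main setting and 44.9% with that normexp setting. Over the scalings fixed beforehand without normexp it lay from 49.4% (cyclic loess) to 54.9% (median scaling). It was 72.0% without scaling and 99.1% with spike-ins, both chosen after seeing the data, so the split depends on such choices.

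**Figure D2:**
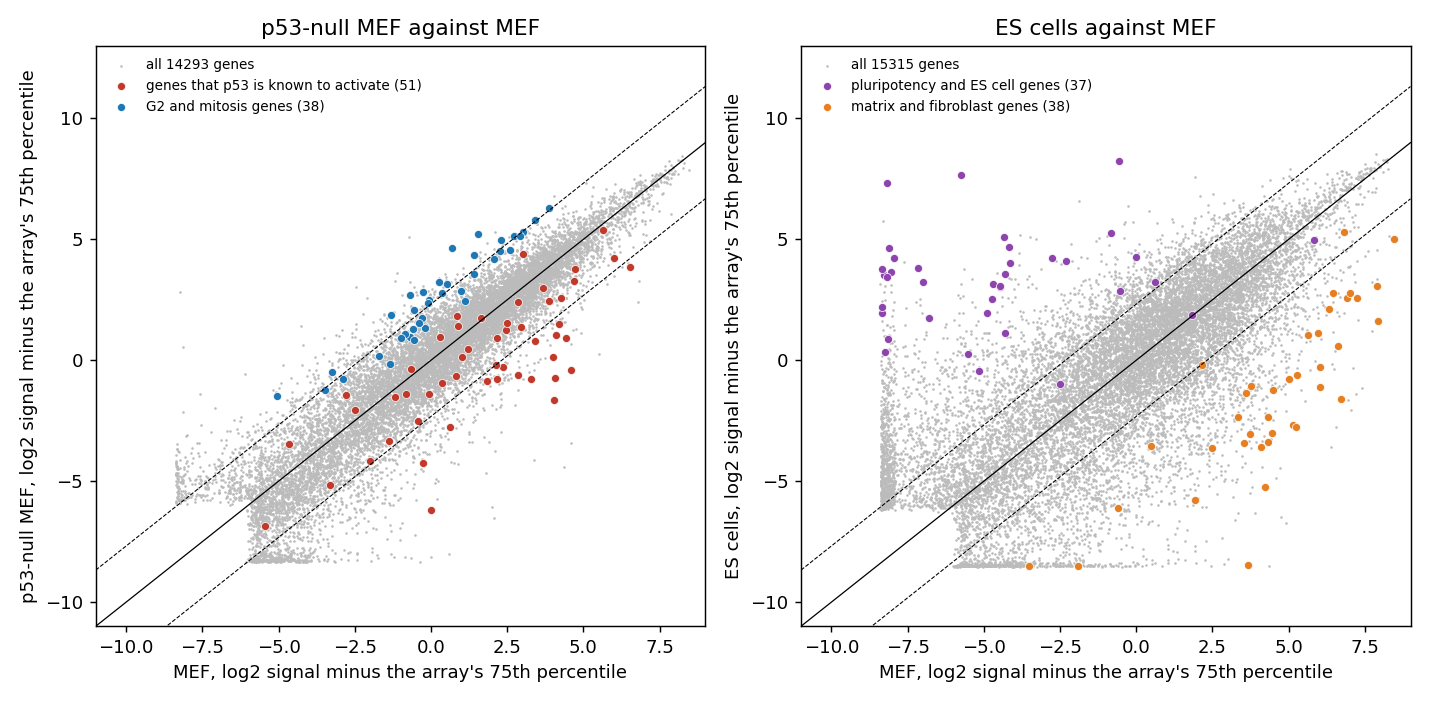
Log2 signal minus the 75th percentile of the array for each gene, with MEF on the horizontal axis and p53-null MEF (left) or ES cells (right) on the vertical axis. The solid line marks equal values and the dashed lines a 5-fold difference. All 38 G2 and mitosis genes lie above the solid line on the left, and all 38 matrix and fibroblast genes lie below it on the right.

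ES cells were compared with MEF to set the pluripotent state beside the cells of origin, on arrays of the same slide. Pluripotency genes were far higher in ES cells. Pou5f1, which encodes the factor Oct4, was at least 764-fold higher, Nanog at least 639-fold and Sox2 128-fold. The threonine dehydrogenase gene Tdh, at 168690 units in ES cells, was 10964-fold higher, and Zfp42, also known as Rex1, at least 10656-fold. In MEF, Tdh (15.3 units), Pipox (16.3) and Tdrd12 (15.2) were near the lowest signal well above background there, 12.4 units. The folds given for them, here and below, are therefore uncertain. Matrix and fibroblast genes were lower in ES cells, where the collagen gene Col12a1 was 720-fold, Col3a1 319-fold and Col6a3 257-fold lower and the proteoglycan gene Lum at least 1059-fold lower.

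Of 37 pluripotency genes, 35 were at least 2-fold higher in ES cells and 0 lower, with a median log2 difference of 7.80 at percentile 100, and 14 of them were measured as bounds. The nuclear receptor gene Nr0b1 was at least 1688-fold higher and Cdh1, the E-cadherin gene, at least 1269-fold. Factors used to make iPS cells had a median of 2.62 at percentile 100. Esrrb was at least 832-fold higher, Lin28a at least 222-fold, Mycn 68.9-fold, Klf5 6.15-fold, Mycl 3.79-fold, Myc 3.54-fold and Sall4 2.89-fold. Glis1 was 10.7-fold lower, and Klf4 and Klf2 differed by -0.28 and -0.83 on the log2 scale, with another Klf2 probe at 3.44. Germ line genes were at 4.75, with 22 of 23 at least 2-fold higher, among them the piRNA pathway genes Tdrd12 at 481-fold and Mael at least 138-fold. Chromatin genes were at 2.88, led by the DNA methylation genes Dnmt3l at 692-fold and Dnmt3b at 287-fold. Both lists lay at percentile 100.

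All 38 matrix and fibroblast genes were at least 2-fold lower in ES cells, with a median log2 difference of -5.73 at percentile 0. Mesenchymal transcription factors were at -4.07, with 32 of 36 at least 2-fold lower, among them the limb factor gene Tbx5 at least 170-fold and Prrx1 118-fold. Epithelial genes were at a median of 16.0-fold higher, with 22 of 29 at least 2-fold higher, among them Epcam at least 740-fold and the factor Grhl2 at least 480-fold. Hox genes were at -4.03, with 29 of 35 at least 2-fold lower, including Hoxc6 at 89.6-fold and Hoxa11 at 55.1-fold. Smooth muscle genes were at -3.86, with the myosin kinase gene Mylk 207-fold and Acta2 92.1-fold lower, with another Acta2 probe at -2.05 on the log2 scale. TGF-beta and BMP genes were at -3.16, with the receptor gene Tgfbr2 78.6-fold lower. Percentiles were 100 for epithelial genes and 0 for the other lists named in these sentences.

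Secreted inflammatory genes were at a median of -4.47 in ES cells against MEF and interferon-stimulated genes at -2.57, both at percentile 0. The growth factor binding gene Igfbp5 was 1210-fold lower, from a signal not well above background in ES cells. The chemokine gene Ccl7 was 295-fold lower, and the antiviral genes Ifit3 and Isg15 were 136-fold and 67.7-fold lower. Bone and cartilage genes were at -2.50 and adipocyte genes at -2.49, both at percentile 0, with Col11a1 76.8-fold and the fatty acid carrier gene Fabp4 212-fold lower, while Alpl, the alkaline phosphatase gene that is also active in ES cells, was 57.5-fold higher. Imprinted genes, at -0.89 and percentile 1.20, went both ways, with H19 382-fold and Igf2 174-fold lower and Phlda2 220-fold higher (6.73 on the log2 scale at another probe). Without a filter on dim probes imprinted genes were at percentile 2.775 and adipocyte genes at 6.63, while imprinted genes were at 21.75 with the mean of all probes and 3.1 with the median probe, so that these lists no longer stood apart.

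G2 and mitosis genes were at 3.17 and replication genes at 3.02 in ES cells against MEF, both at percentile 100. At least 2-fold higher were 37 of 38 and 36 of 36, among them Ttk at 41.8-fold and the origin recognition gene Orc1 at 36.3-fold. Trp53 itself was 3.73-fold higher in ES cells at the brighter probe and differed by -0.92 at the other. Its list of relatives and regulators was at 1.47 and percentile 99.1 (96.4 with the median probe, which ends the call), where Chek1 was 33.7-fold higher. Genes activated by p53 were at -0.47 and percentile 4.90, with 22 of 52 at least 2-fold lower and 9 higher. With the median probe these genes were at -0.77 and percentile 1.25 and stood apart. Among them the tetraspanin gene Cd82 was 63.8-fold, Ephx1 38.2-fold, the death receptor gene Fas 35.9-fold and Cdkn1a 25.9-fold lower.

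Of the other genes remembered as followed up by the study, Zmat3 was 2.36-fold and Arhgap18 5.33-fold lower in ES cells than in MEF. Mdm2 differed by 0.02 on the log2 scale and Inmt was not well above background. That list was at -1.83 and percentile 6.87. The list of CDK inhibitors, Rb family, E2f, D-type cyclin and Cdk genes was at -0.62. In it the inhibitor genes Cdkn2b and Cdkn2c were 32.9-fold and 15.9-fold lower, and the cyclin gene Ccnd2 15.2-fold lower. Early lineage genes were at 1.24 and percentile 98.4, with the trophoblast factor gene Tfap2c at least 178-fold higher and Pdgfra 70.4-fold lower, and their median turned to -2.76 among genes measured on both arrays. They no longer stood apart with quantile normalization (percentile 97.1), either normexp setting (94.0 and 94.8) or the mean of all probes (95.2). Medians of lists that did not stand apart were -0.88 for skeletal muscle, -0.60 for macrophage, -0.08 for endothelial, -0.02 for neural, -0.30 for glycolysis and hypoxia genes, 0.27 for expression references and 1.60 for Xist and Y chromosome genes.

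Among single genes, Pipox was 701-fold, Bex1 513-fold, the F-box gene Fbxo15 475-fold, Dppa5a 452-fold (10.8 on the log2 scale at another probe) and the POU factor gene Pou3f1 385-fold higher in ES cells than in MEF, and Tcf15 at least 3615-fold. The mineralisation inhibitor gene Mgp was 1014-fold lower, Prelp 712-fold, Ccdc80 626-fold, Cbr2 605-fold, Ly6a, the gene of the surface antigen Sca-1, 573-fold, Ly6c1 541-fold and Ccn5 521-fold. Lrrc17, the thrombomodulin gene Thbd and Prg4 were at least 2491-fold, 2228-fold and 1696-fold lower. In all, 2453 gene labels were at least 5-fold higher and 2446 at least 5-fold lower, out of 18745 well above background on at least 1 array, with 751 and 562 of them counted by a bound. Among genes matched to RefSeq the counts were 1875 and 2281. With normexp correction and 75th percentile scaling they were 1454 and 1549 labels. With p53-null MEF in place of MEF, 1052 of the 1875 matched genes higher in ES cells and 1418 of the 2281 lower ones were at least 5-fold different in the same direction.

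**Figure D3:**
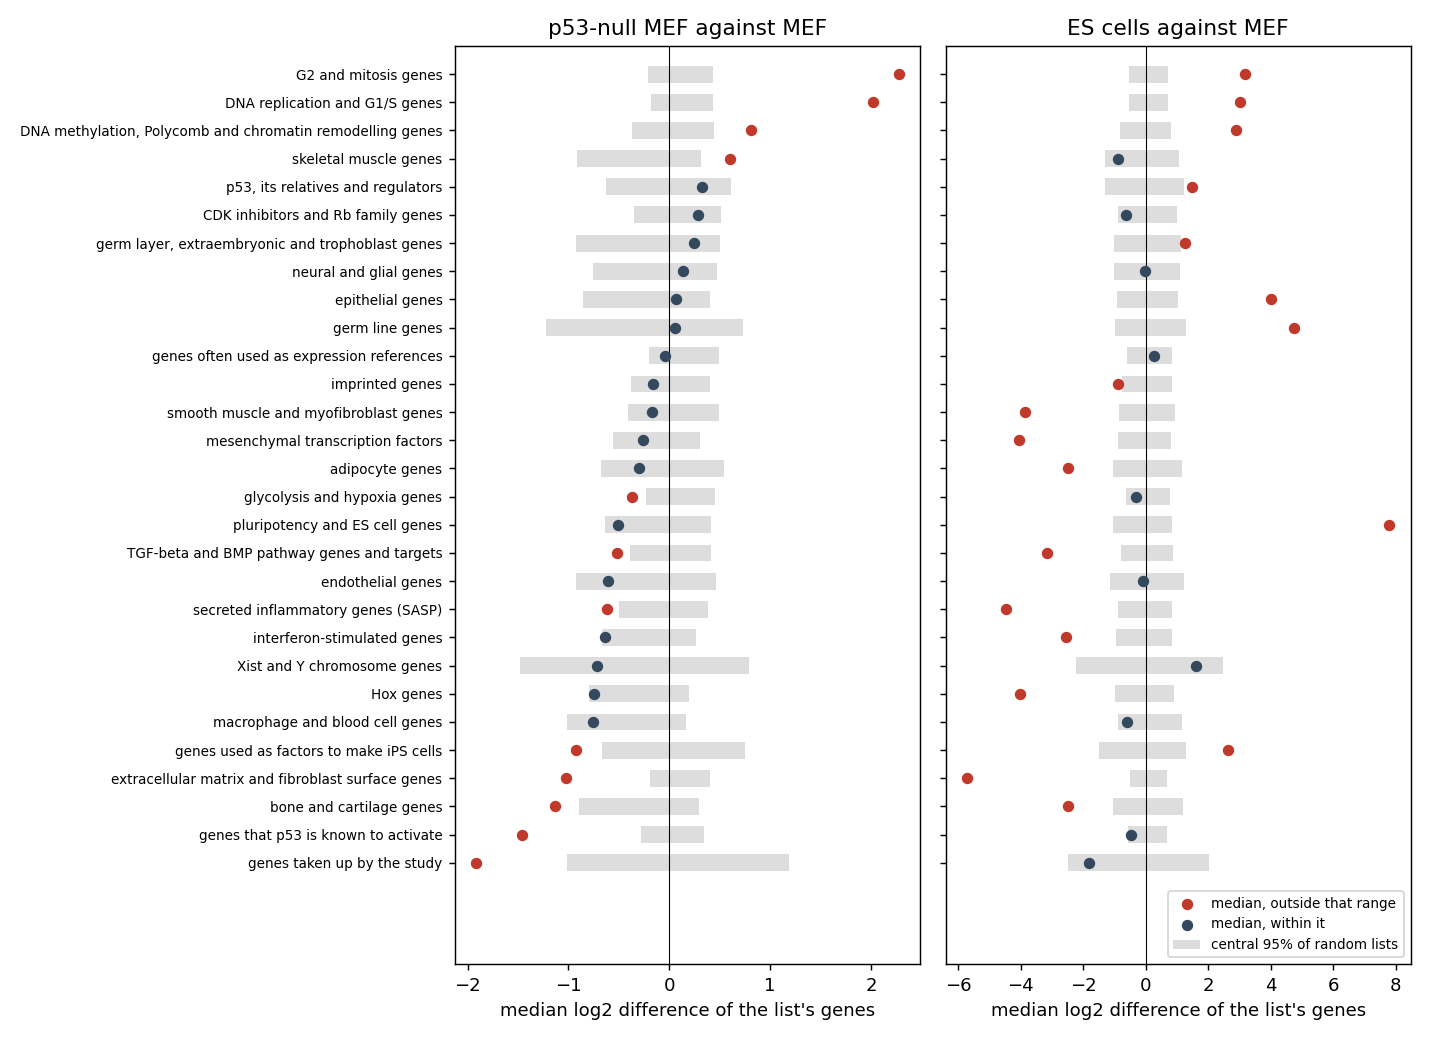
Median log2 difference of each of 29 gene lists (points) in p53-null MEF against MEF (left) and ES cells against MEF (right), with grey bars for the central 95% of 10000 random lists of matched signal. G2 and mitosis genes lie at 2.28 on the left and 3.17 on the right, and matrix and fibroblast genes at -1.03 (0.94 with scaling on spike-ins, which shifts all genes) and -5.73.

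The difference of ES cells from the mean of both fibroblast arrays was set against the difference of p53-null MEF from MEF, to see whether genes that differ with p53 also differ in the pluripotent state. The overlap of calls was taken over 14138 matched genes with a value or bound in both comparisons, which leaves out part of the calls counted above. Among these, 312 genes were at least 5-fold higher and 495 lower in p53-null MEF, and 1452 were higher and 2281 lower in ES cells than in MEF. Of the 312, 207 were at least 5-fold higher in ES cells than in MEF and 11 lower. Of the 495, 306 were lower in ES cells and 13 higher. Lists of these sizes drawn independently from these genes would share 32.0 higher and 79.9 lower genes. An unchanged array simulated with the noise of repeated spots gave 0 genes to share, but that noise is too small for any call at 5-fold and leaves out differences between cultures and slides, so this 0 sets no chance level for the overlap. Part of the excess may come from the MEF array, which both comparisons share and which had the lowest signals of G2 and mitosis genes such as Mki67 and Ttk. Across 12356 genes well above background on all arrays, which are not independent replicates, Pearson's r was 0.30 and Spearman's rho 0.35. The centred difference still holds both fibroblast arrays. Centring removes the covariance from sharing them only if both vary alike, so a MEF array particular in itself could give such an r. The covariance was 0.658, against -0.00608 in simulations of an unchanged array, which again hold spot noise alone and so do not show that the p53 and pluripotency differences are linked. By construction 0.658 lies midway between the covariances with ES cells minus MEF, 1.29, and with ES cells minus p53-null MEF, 0.0302. With ES cells minus p53-null MEF in place of the centred difference, r was 0.01. That difference shares the p53-null MEF array with the opposite sign, which pulls r down, to -0.05 in simulations with spot noise alone. An r near 0 there is thus not an unbiased check.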

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

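The alternatives without scaling, with spike-in scaling, with GC correction, with matched genes alone and with p53-null MEF in place of MEF were chosen after seeing the data. In p53-null MEF against MEF, labels at least 5-fold higher and lower numbered 583 and 530. Counts within 1.5 times of these ranged from 438 to 621 higher over 10 alternatives and from 374 to 568 lower over 12. They were 199 and 244 with normexp and 75th percentile scaling and 197 and 247 with normexp and quantile normalization, which change the signal, the background method and the offset together, so the cause was not tested. They were 1033 and 1033 without a filter on dim probes, 3233 and 2895 at 2-fold and 112 and 191 at 10-fold, by construction. Higher labels numbered 961 without scaling and 323 among matched genes. With scaling on spike-ins, whose median was 7069 units on the p53-null MEF array against 22095 on the MEF array, 6554 labels were higher and 60 lower. The share of higher among these labels was 52.4% in the main setting, 54.9% with median scaling, 49.4% with cyclic loess, 72.0% without scaling and 99.1% with spike-ins. The median of all labels measured on both arrays was 0.05 in the main setting, 0.38 without scaling and 2.02 with spike-ins, and in ES cells against MEF 0.14, 0.15 and 0.41, with -0.08 for median scaling, -0.06 for cyclic loess and 0.02 for GC correction.

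In ES cells against MEF, counts stayed between 1702 and 3330 higher and between 1884 and 3084 lower over 14 and 15 alternatives. They were 1454 and 1549 with normexp and the 75th percentile, 1446 and 1608 with normexp and quantiles, 6137 and 5089 at 2-fold and 1159 and 1354 at 10-fold, and 1594 higher with p53-null MEF in place of MEF. The Trp53 difference of -4.87 stayed between -4.93 and -4.78 in 9 alternatives. It was -3.81 and -3.70 with the normexp settings, -3.16 as a mean of both probes, -4.54 without scaling, -2.89 with spike-ins and -4.57 with GC correction. The correlation of 0.302 was 0.320 and 0.339 with the normexp settings. With ES cells minus MEF, which shares the MEF array in full where the centred difference shares it in part, the correlation was 0.526. It was 0.0145 with ES cells minus p53-null MEF, which shares the p53-null MEF array with the opposite sign.

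Medians of G2 and mitosis genes (2.13 to 4.25), pluripotency genes (6.13 to 8.16) and matrix and fibroblast genes in ES cells (-5.95 to -4.87) kept their direction and stood apart in each alternative run. P53-activated genes in p53-null MEF (-1.78 to -1.13) stood apart in each too, and their median changed sign with spike-ins alone. Scaling on spike-ins shifts all differences measured on both arrays alike, while a bound that it takes past 0 was set to 0. In p53-null MEF against MEF it turned the medians of p53-activated genes to 0.375, of the followed-up genes to 0.0580, of iPS factors to 1.05 and of matrix and fibroblast genes to 0.945. Medians of secreted inflammatory genes turned to 1.35, of TGF-beta and BMP genes to 1.40, of bone and cartilage genes to 0.835 and of glycolysis and hypoxia genes to 1.61. All lie under 2.02, the median of all labels measured on both arrays in that setting. Against random lists of the same setting these medians still stood apart, except bone and cartilage genes at percentile 3.97, so the changes of sign come from the shift. Early lineage genes in ES cells turned to -2.76 among genes measured on both arrays, where bounds are left out. Where no construction is named, the cause was not tested. Median scaling, the 75th percentile of probes well above background and no scaling change only 1 constant per array, and the authors' value table almost nothing. They could hardly move a percentile, and each left all 58 list results in place. Over all lists and alternatives, these included, 888 medians stayed on their side of the percentile limits, 15 lost that place and 17 gained it. Those that lost it were iPS factors, chromatin, TGF-beta and BMP and glycolysis genes in p53-null MEF against MEF, and early lineage, imprinted and adipocyte genes and relatives of p53 in ES cells against MEF, with the percentiles given in the report. Those that gained it were mostly interferon-stimulated, Hox and macrophage genes, lower in p53-null MEF. They also included p53-activated genes in ES cells against MEF, lower with the median probe. Another 9 changed sign, 8 of them through the spike-in shift. Of values of named genes, 2930 moved by less than the error model, 1127 by more, and none at least 5-fold different changed sign. No paired analysis was possible because each group had 1 array. Signal over background limits dim genes, for which bounds alone are given.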

Other observations

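The tests of the second probes and the sex chromosomes were set down before their results were seen. Those of the GC correction, set down once the GC trend had been looked at, of the replication genes and of ES cells against p53-null MEF for unmatched labels were chosen after. ES cells were also set against p53-null MEF, on different slides. Genes activated by p53 were higher in ES cells there, with a median log2 difference of 1.04 at percentile 100 and 26 of 51 at least 2-fold higher. Eda2r had 1409 units in ES cells and was not well above background in p53-null MEF, and Perp had 6308 against 622. G2 and mitosis genes were at 0.78, with 15 of 38 at least 2-fold higher in ES cells. The list of CDK inhibitors, Rb family, E2f, D-type cyclin and Cdk genes was at -1.13 and percentile 0.350. In it Cdkn2b had 1083 units in ES cells against 24412 and Cdkn2c 184 against 5541. Pluripotency genes were at 7.98 and matrix and fibroblast genes at -4.87.

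The interferon-stimulated chemokine genes Cxcl10 and Ccl5 were higher in p53-null MEF than in MEF by 3.96 and 2.58 on the log2 scale, while 12 of 37 genes of that list were at least 2-fold lower. ES cells had Y chromosome signals of Eif2s3y at 4104 units and Ddx3y at 1479, and Kdm5d, at 245 units in MEF, was not well above background in ES cells. Tsix, the antisense RNA of Xist, was at least 39.9-fold higher in ES cells than in MEF.

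The first pattern is the number of genes at least 5-fold different between p53-null MEF and MEF. If probe behaviour on a second slide were its source, other probes of these genes would often disagree. Of 301 such genes with a second probe well above background on at least 1 array, 87.7% had that probe at least 2-fold different in the same direction. Among 5864 genes not called, 35.8% had such a probe at least 2-fold different in either direction. This argues against probe-level effects, though not against a slide effect shared by the probes of a gene. Different sex of the embryos, read from Xist and Eif2s3y, would place the genes on the X and Y chromosomes if it acted on sex-linked genes alone. Of 817 genes, 4.65% lay there against 3.57% of 14275 measured genes, so most of the called genes are not sex-linked. So small a share of the measured genes could hardly have made up the bulk in any case. The test thus gives no evidence against an effect of sex. Effects of sex on genes of other chromosomes were not tested. The p53 genotype, the sex of the embryos, other differences between the 2 cultures and the slide stay open, and they cannot be told apart with 1 array per group.

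The second pattern is the higher level of G2 and mitosis genes such as Cenpe and Mki67 in p53-null MEF. Differences between these arrays ran with the GC content of the probes, with Spearman's rho of -0.24 over 22863 probes. With that trend removed the list's median was 2.21 against 2.28 before, which argues against the GC trend as its source. A more slowly dividing MEF culture may account for it as well as the p53 genotype would, since both predict higher replication genes in p53-null MEF, seen at a median of 2.02, and with 1 culture each these explanations cannot be told apart.

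The third pattern is that gene labels with no RefSeq match were mostly higher in p53-null MEF, with 260 at least 5-fold higher and 35 lower. With the GC trend removed, 83.6% of those counted were higher against 88.1% before, which argues against probe GC content as the whole source. ES cells against MEF, within 1 slide, also had 77.8% of such labels higher, whereas ES cells against p53-null MEF had 52.9%, with 255 higher and 227 lower. By that split a source particular to the MEF array or its RNA could account for the pattern, but the median log2 difference of unmatched labels, at 0.37 in p53-null MEF against MEF, 0.69 in ES cells against MEF and 0.33 in ES cells against p53-null MEF, rose over the 3 arrays and did not single out MEF. With 1 array per group this explanation and a difference in slide stay open, and which RNAs these labels stand for was not determined.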
